A study of Mus musculus with 12 samples.

How the data were processed

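RNA was measured in 12 libraries of mouse primary hepatocytes, 3 in each of 4 groups: WT or Fxr-/- cells treated with AC or FAC at 100 µM for 24 h. Per the submitters' processing notes, reads were quantified with RSEM against mm10 and GRCm38.p6 (versions not given in the sources used here). The libraries were prepared for a BGISEQ-500 sequencer, per the labels' protocols. The aligner, the annotation release, the strand setting and any filter are not stated. The authors deposited estimated counts per gene and library without normalization. They also deposited FPKM values, scaled by gene length and library total, and TPM values, which summed to 1000000 in each library except WT FAC 5 (999999). The deposited group means of the estimated counts were used only to check which libraries the authors averaged, and 8 further numeric columns were not mapped to a library and not used here.

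The table held 16728 genes. Of their identifiers 16629 matched the reference list of gene names, which also gave positions in GRCm38.p6. Symbols that a spreadsheet had turned into dates or numbers numbered 28, and 22 of them were restored through the identifier. Library totals ranged from 16464494 to 18335700 estimated reads. Estimated counts were rounded, scaled by the TMM method and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 12275 genes and removed 4453. A robust quasi-likelihood model with a trended dispersion was fitted to the 4 groups, and 5 contrasts were tested: FAC against AC in WT, FAC against AC in KO, the difference of these effects (KO minus WT), and KO against WT under AC and under FAC. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. It was derived from the test and not estimated separately. The biological coefficient of variation was 10.8%. The plan written before the data were examined gave limma on log2(FPKM + 1) as the test for FPKM values and edgeR as the main test where counts exist, with limma then an alternative. Estimated counts exist, so edgeR was used.

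Before the data were examined, 37 lists of 694 genes were fixed, covering bile acids and Fxr targets, iron and hepcidin, stress responses, metabolism, hepatocyte identity and zonation, inflammation, growth, and markers of other cell types. A total of 33 lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation, and with fry. Counts of called members were made over all genes and adjusted over the list alone. Genes named in the text follow a rule also fixed then. It names 16 genes of Fxr, bile acid and iron biology in every comparison. It adds up to 4 called members with the largest fold in each list that was called or had at least 3 called members. It further adds the 8 called genes most higher and the 8 most lower, with a mean FPKM of at least 5 in a compared group and no overlap of libraries (overlap was not asked of the difference). Where fewer than 5 genes were called it adds those with the smallest p. Sums over near-identical genes, and the naming of Hamp2 beside Hamp and of genes near Nr1h4, were chosen after the values of single genes were seen. A pair of genes that the rule names for the difference is not reported here, though they are included in the counts.

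Alternatives fixed at the same time were a pseudocount of 0.1 on FPKM, no filter, a filter of FPKM at least 5 in 3 samples, median-of-ratios scaling, TPM values, a fit of the compared pair of groups alone, a fit without trend and robust, a 2-fold threshold, the replicate number as a block, an estimated correlation, and each library left out in turn. Limma on log2(FPKM + 1) was the alternative that the plan gave for a table with counts. Added after the data were seen were DESeq2 1.42.0, TMM factors without Mup genes, and the fits without KO AC 1 and KO FAC 6 and without KO AC 1 and KO FAC 4. Splits of the libraries into other groups were fitted in the same way, 10 for each pair of groups and 100 for the difference. Figures were drawn with matplotlib 3.10.9.

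The model was tested on simulated data with 200 changed genes among 12275 in each comparison. For FAC in WT, 67.2% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 92.4% of those changed 4-fold were recovered, and 6.29% of calls were false. For FAC in KO these values were 41.8%, 76.1%, 93.9% and 4.73%. For the difference they were 22.4%, 67.2%, 87.9% and 7.81%. For KO under AC they were 43.3%, 79.1%, 92.4% and 5.92%, and for KO under FAC 65.7%, 80.6%, 95.5% and 6.94%. In the simulation of FAC in WT a moved list had a camera p of 1.46e-82, and 3 of 200 random lists passed. Genes were drawn independently there, so the simulation did not test camera on lists of correlated genes. Every group was simulated with the same mean and the same dispersion per gene, apart from the changed genes. A larger spread between KO than WT libraries was therefore not simulated. The values above do not rank the 4 comparisons of 2 groups by power, since these differ mainly in the genes drawn.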

Results

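RNA of mouse primary hepatocytes was sequenced in 12 libraries to ask how iron overload, named in the series title, acts on cells with and without Fxr. Fxr (gene Nr1h4) is a nuclear receptor activated by bile acids. The cells were wild-type (WT) or Fxr-/- (KO) and were treated for 24 h with FAC at 100 µM or AC at 100 µM. The labels give FAC and AC only as abbreviations. Each of the 4 groups (WT AC, WT FAC, KO AC, KO FAC) had 3 libraries, numbered 1 to 3 under AC and 4 to 6 under FAC, and all were labelled with the strain C57BL/6. Depth ranged from 16464494 to 18335700 estimated reads per library, and 14243 to 14481 genes had at least 1 read. Of the 16728 genes listed, 12275 passed the filter on low counts and were tested. The labels do not say whether the libraries of a group come from separate animals or cultures, so every p-value measures only the spread between these samples. Genes that share reads with near-identical copies (the Mup family, Hspa1a and Hspa1b, Hamp and Hamp2) carry an uncertain split of reads, and the strand setting of the counting is not stated.

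Nr1h4 (gene identifier 20186, chromosome 10, 89454234 to 89533645 in GRCm38) was read in every library. Its level was 13.0, 15.6 and 13.1 CPM (estimated reads per 1000000 reads of the scaled library) in the WT AC libraries and 7.00, 6.95 and 7.69 in the WT FAC libraries. It was 9.35, 6.97 and 7.45 in the KO AC libraries and 3.54, 4.45 and 4.89 in the KO FAC libraries. The KO libraries lay below the WT libraries of the same treatment in all 6 cases, at log2 fold changes of −0.81 ± 0.14 (SE) under AC and −0.75 ± 0.16 under FAC (edgeR adjusted p = 0.000535 and 0.00157). Reads of a transcript from which part is deleted can remain, and these counts cover the whole gene, so they give no test of the deletion itself. FAC lowered Nr1h4 in WT cells, from 13.9 ± 1.5 to 7.21 ± 0.41 CPM (SD, n = 3; edgeR adjusted p = 0.00063), and in KO cells, from 7.92 ± 1.26 to 4.29 ± 0.69 CPM (edgeR adjusted p = 0.00124). The first principal component of the libraries held 59.2% of the variance and separated all 6 KO from all 6 WT libraries. The second component held 16.2% and the third 7.42%. On the third, KO AC 1, KO FAC 5 and KO FAC 6 lay on one side (13.5, 3.26 and 27.7). KO AC 2, KO AC 3 and KO FAC 4 lay on the other (−14.6, −9.63 and −22.7). Without KO AC 1 and KO FAC 4, treatment in KO cells coincides with this division.

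The first comparison asked how FAC changed WT hepatocytes. Hamp (chromosome 7, 30942368 to 30944029), which encodes the iron hormone hepcidin, fell from 323 ± 23 to 15.7 ± 5.3 CPM (SD, n = 3), a log2 fold change of −4.36 ± 0.42 (SE, edgeR adjusted p = 0.0002). The BMP target genes Id1 and Id2 and the transcription factor gene Atoh8 fell with it, at log2 fold changes of −1.97 ± 0.16, −3.14 ± 0.32 and −4.06 ± 0.35. Tfrc, which encodes the transferrin receptor, fell from 83.7 to 38.4 CPM (−1.13 ± 0.16), and the ferritin light chain gene Ftl1 rose from 3946 to 6822 CPM (0.79 ± 0.08). The inducible chaperone genes Hspa1a and Hspa1b rose most of the genes named here, Hspa1a from 1.89 ± 0.15 to 46.2 ± 4.3 CPM (log2 fold change 4.61 ± 0.20, edgeR adjusted p = 2.27e-08). In Hamp, Id1, Tfrc, Ftl1, Hspa1a and Hspa1b the 3 FAC libraries lay on one side of the 3 AC libraries.

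**Figure D1:**
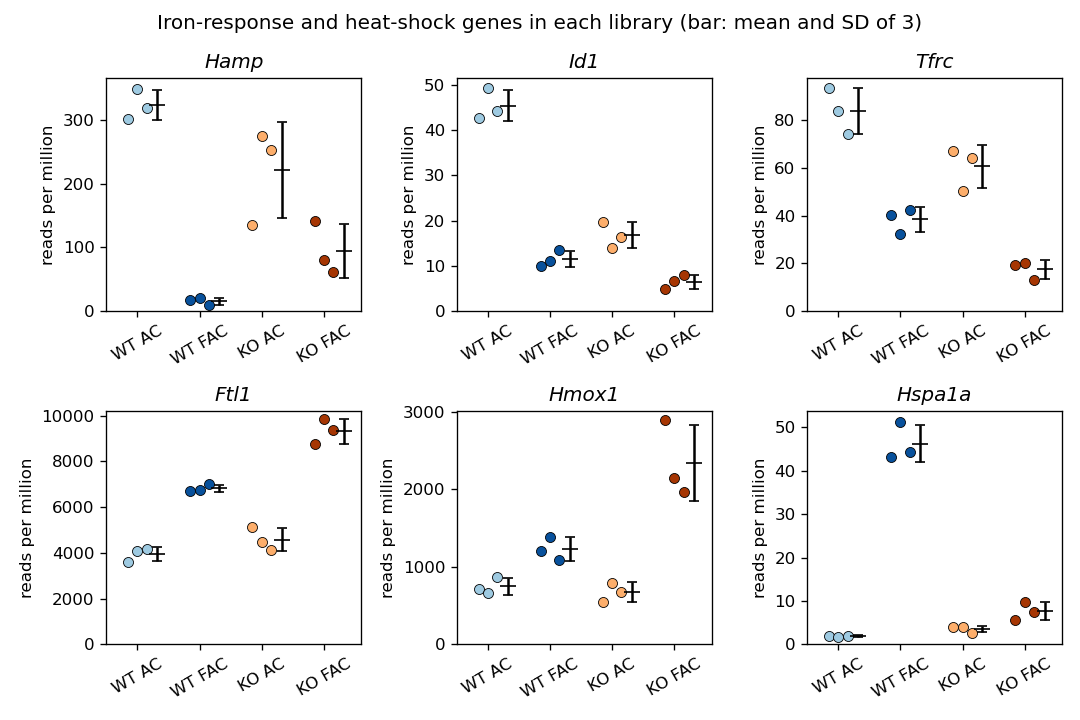
Level of 6 genes in each library, in CPM, for the 4 groups; points are libraries, and the bar and whiskers are the mean and SD of the 3 libraries of a group. Hspa1a sat at 46.2 CPM in WT FAC and 7.60 CPM in KO FAC, while Tfrc was lower and Ftl1 higher with FAC in both genotypes.

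In all, 2117 of the 12275 genes (17.2%) changed with FAC in WT cells at an edgeR quasi-likelihood p under 0.05 after Benjamini-Hochberg adjustment, 1068 higher and 1049 lower. Of these, 290 changed at least 2-fold. The FAC and AC libraries did not overlap for 5301 genes (43.2%), where chance gives 10%. A permutation test of 3 against 3 libraries allows no p below 0.1. The count was over 1.5 times lower without 1 library in 4 cases: 1303 without WT AC 3, 1330 without WT FAC 4, 1264 without WT FAC 5 and 1373 without WT FAC 6. A fit of the WT libraries alone called 3352. The division into higher and lower genes depended on scaling: 22.3% were higher with TPM values, whose median shift over all genes was −0.109, against 50.4% here.

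Among the lists fixed beforehand, the BMP and hepcidin genes fell: 7 of 15 tested members were lower and none higher (adjusted over the list alone, 10 lower and 1 higher), with a list median of −0.45. Camera, a test of the list against all other genes, gave an adjusted p of 1.72e-08, and 0.00694 with an estimated correlation. Smad7, an inhibitor of BMP signalling, was at −0.48 ± 0.17 and missed the threshold (edgeR adjusted p = 0.0677), but passed at 0.0019 in the fit of the WT libraries alone, 0.0466 with DESeq2 and 0.0412 with TPM values. The list of iron uptake, storage and export genes had 4 members higher, 3 lower and 14 not passing (adjusted over the list alone, 5 and 3), and no call (camera adjusted p = 0.825). Besides Ftl1, the iron exporter gene Slc40a1 rose (0.79 ± 0.18, edgeR adjusted p = 0.0126, and 0.0519 without WT AC 1, in a range from 5.38e-06 over its alternatives), and the ferroxidase gene Cp fell (−0.82 ± 0.09). The ferritin heavy chain gene Fth1 rose by less (0.33 ± 0.09, edgeR adjusted p = 0.0282). Its call was lost without WT AC 1, WT AC 2, WT FAC 4, WT FAC 5 or WT FAC 6 (0.107, 0.0551, 0.0983, 0.0751 and 0.0518), with TPM values (0.0642), and without trend and robust (0.0528). The haem-degrading enzyme gene Hmox1 rose by 0.71 ± 0.17 (edgeR adjusted p = 0.018), and missed the threshold without WT AC 1, WT AC 2 or WT FAC 5 (0.0759, 0.0669 and 0.0688).

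Stress genes followed. The heat-shock list had 3 of 12 members higher (Hspa1a, Hspa1b and the co-chaperone gene Dnajb1 at 0.37 ± 0.07) and none lower (adjusted over the list alone, 4 higher and 1 lower; camera adjusted p = 1.72e-08, and 0.00665 with an estimated correlation). The list median was 0.149 and the mean 0.725, and the list was not tested without Hspa1a and Hspa1b in this comparison. Of 27 genes of endoplasmic reticulum stress and the integrated stress response, 14 rose and none fell (adjusted over the list alone, 15 and 1), with a median of 0.31 (camera adjusted p = 3.5e-08, and adjusted p = 0.0722 with an estimated correlation). Ddit3, a transcription factor gene of that response, rose from 20.5 ± 2.8 to 71.5 ± 2.8 CPM (1.80 ± 0.09), and Chac1, which encodes a glutathione-degrading enzyme, rose by 0.82 ± 0.15. Of 22 autophagy and lysosome genes, 10 rose and 1 fell (adjusted over the list alone, 12 and 3; camera adjusted p = 0.000445, and adjusted p = 0.273 with an estimated correlation), among them Gpnmb (0.70 ± 0.07), Neu1 (0.64 ± 0.06) and Ctsl (0.52 ± 0.06). The ferroptosis genes had 3 higher, 4 lower and 19 not passing (adjusted over the list alone, 3 and 5), and the Nrf2 targets 3 higher and 7 lower of 30 (adjusted over the list alone, 4 and 9). Neither list was called (camera adjusted p = 0.986 and 0.413), and for both the median was above 0 and the mean below it. Gclc, the rate-limiting enzyme gene of glutathione synthesis, fell (−0.64 ± 0.10). The cystine transporter gene Slc7a11 (0.10 ± 0.20) and the lipid peroxide reductase gene Gpx4 (0.22 ± 0.10) did not pass (edgeR adjusted p = 0.776 and 0.136), but Gpx4 passed in the fit of the WT libraries alone (0.0435).

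Some lists of metabolic and hepatocyte genes were called higher and others were not called. The xenobiotic enzyme list had 10 of 21 members higher and none lower (adjusted over the list alone, 10 and 2; median 0.32; camera adjusted p = 0.000445, and 0.05, just under the threshold before rounding, with an estimated correlation). Cyp2b10 (1.78 ± 0.17), Cyp2c29 (1.01 ± 0.11) and Cyp3a11 (0.75 ± 0.11) were among them. Hepatocyte identity genes had 9 higher and 4 lower of 23 (adjusted over the list alone, 11 and 5; median 0.44; camera adjusted p = 0.000445, and adjusted p = 0.389 with an estimated correlation). Tdo2 (1.02 ± 0.16), Apoa1 (0.94 ± 0.08) and Ttr (0.82 ± 0.07) were among those that rose and Hgd (−1.09 ± 0.23) among those that fell. Of 25 cholesterol synthesis genes, 11 rose and 2 fell (adjusted over the list alone, 14 and 2; camera adjusted p = 0.000772, and adjusted p = 0.346 with an estimated correlation), with Insig1 at 0.69 ± 0.14. Sex-biased liver genes had 6 of 12 higher (adjusted over the list alone, 7; camera adjusted p = 0.00162, and adjusted p = 0.273 with an estimated correlation). Bile acid synthesis genes had 4 of 16 higher (adjusted over the list alone, 4; camera adjusted p = 0.0349, and adjusted p = 0.603 with an estimated correlation). The latter call was lost in the fit of the WT libraries alone (0.0641), under the stricter filter (0.0559) and without WT AC 1, WT AC 3 or WT FAC 6 (0.0613, 0.0568 and 0.0505). Not called were lipogenesis (3 lower and 0 higher of 20, median −0.06), gluconeogenesis and glycolysis (3 lower and 0 higher of 20) and PPARα targets and fatty acid oxidation (3 higher and 2 lower of 25), at camera adjusted p = 0.122, 0.463 and 0.783. Adjusted over each list alone, 4 and 3 members were lower in the first and second, and 4 were higher and 2 lower in the third. In the second the median lay above 0 where the test pointed down, and in the third below 0 where it pointed up. Of the genes tied to Fxr, Nr0b2, Abcb11 and Cyp8b1 did not pass in WT cells (edgeR adjusted p = 0.128, 0.877 and 0.451), though Nr0b2 (0.0144) and Cyp8b1 (0.0412) did in the fit of the WT libraries alone. Nr0b2 had few reads: 57 summed over WT AC, 19 over WT FAC, 23 over KO AC and 16 over KO FAC. A missed threshold for Nr0b2 in any comparison therefore does not show that it was unchanged. The list of genes induced by Fxr had 6 higher and 1 lower of 21 (adjusted over the list alone, 7 and 4; median 0.33). It just missed the threshold (camera adjusted p = 0.0505, and adjusted p = 0.603 with an estimated correlation). Cyp7a1 and Slc51b had at most 23 reads summed over any group and were not tested. Markers of other cell types moved as well: sinusoidal endothelial markers had 5 of 14 higher (adjusted over the list alone, 7; camera adjusted p = 0.00168, and adjusted p = 0.0722 with an estimated correlation), with Pecam1 from 4.35 to 7.46 CPM. Of the macrophage markers, Adgre1 (2.23 to 0.71 CPM) and Marco fell and Cd68 rose (387 to 671 CPM). The macrophage list had no call (camera adjusted p = 0.845), with a median of 0.22 and a mean of −0.15. On the log2(FPKM + 1) scale, 13 of 105 named genes had folds over 1.5 times smaller, and with TPM values 20 had. Atoh8, Cyp2b10 and Pecam1 were among them in both, and Fth1 with TPM values.

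The next comparison asked the same of KO hepatocytes. Tfrc fell from 60.6 ± 8.9 to 17.5 ± 3.8 CPM (SD, n = 3; log2 fold change −1.80 ± 0.17, SE, edgeR adjusted p = 2.09e-05), and Ftl1 rose from 4572 to 9323 CPM (1.03 ± 0.08). Hmox1 rose from 670 ± 127 to 2335 ± 487 CPM (1.80 ± 0.18), and Slc40a1 (1.05 ± 0.19) and Fth1 (0.56 ± 0.09) rose too. Star, which encodes a cholesterol carrier of mitochondria, rose from 7.13 ± 1.66 to 61.1 ± 10.2 CPM (3.10 ± 0.21). Hamp fell from 221 ± 75 to 94.8 ± 41.5 CPM (−1.22 ± 0.37, edgeR adjusted p = 0.0336), with overlapping libraries, while its copy Hamp2 rose (1.75 ± 0.14). The Hamp call was lost without KO AC 2 (0.0954), KO AC 3 (0.0989), KO FAC 5 (0.101) or KO FAC 6 (0.0719), in the fit of the KO libraries alone (0.111), with no filter (0.057), and when reads of both copies were summed (−0.78 ± 0.30, edgeR adjusted p = 0.08).

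FAC changed 3633 genes in KO cells (29.6%; edgeR quasi-likelihood, Benjamini-Hochberg), 1838 higher and 1795 lower, and 487 of them at least 2-fold. Libraries did not overlap for 4762 genes (38.8%; chance 10%). Without KO AC 3 the count was 2365, and a fit of the KO libraries alone called 2198. That fit reverses the order of the counts in WT and KO cells, so the counts do not rank the genotypes. With TPM values 741 of 4498 called genes were higher, and the median shift over all genes was −0.181. The share that was higher was 32.0% with log2(FPKM + 1) and 31.4% with a pseudocount of 0.1, against 50.6% here.

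In KO cells the xenobiotic enzyme list had 15 of 21 members higher and none lower (adjusted over the list alone, 15; median 0.67; camera adjusted p = 9.99e-13, and 0.0028 with an estimated correlation), with Cyp2c29 (1.10 ± 0.10), Cyp2b10 (1.08 ± 0.11) and Cyp3a25 (1.01 ± 0.09). Of the genes of endoplasmic reticulum stress and the integrated stress response, 16 of 27 rose (adjusted over the list alone, 17 higher and 1 lower; camera adjusted p = 4.2e-10, and adjusted p = 0.0915 with an estimated correlation). The members that rose most were the serine synthesis genes Phgdh (1.42 ± 0.07) and Psat1 (1.07 ± 0.09) and the chaperone-related gene Creld2 (1.40 ± 0.08). The hepatocyte identity list had 15 higher and 2 lower of 23 (adjusted over the list alone, 15 and 3; median 0.45; camera adjusted p = 1.61e-07, and adjusted p = 0.192 with an estimated correlation). Cholesterol synthesis had 15 higher and 1 lower of 25 (adjusted over the list alone, 17 and 1; camera adjusted p = 4.28e-05, and adjusted p = 0.215 with an estimated correlation), with Insig1 at 1.02 ± 0.14. Pericentral genes had 9 higher and 1 lower of 16 (adjusted over the list alone, 10 and 1; camera adjusted p = 0.000178, and adjusted p = 0.192 with an estimated correlation), Cyp2e1 at 0.78 ± 0.08. Sex-biased genes had 8 of 12 higher (adjusted over the list alone, 9; camera adjusted p = 0.000179, and adjusted p = 0.192 with an estimated correlation).

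Lists of bile acid genes were called higher in KO cells as well, though not with an estimated correlation. Of 21 genes listed as induced by Fxr, 10 rose and 1 fell (adjusted over the list alone, 12 and 1; camera adjusted p = 0.000281, and adjusted p = 0.227 with an estimated correlation). They included Abcb11, the bile salt export pump gene (2.18 to 4.57 CPM, 1.06 ± 0.20), and the fibrinogen genes Fga (1.31 ± 0.12) and Fgg (1.13 ± 0.13). Bile acid synthesis genes had 6 of 16 higher (adjusted over the list alone, 6; camera adjusted p = 0.00108, and adjusted p = 0.318 with an estimated correlation), with Akr1c6 at 1.67 ± 0.14. Cyp8b1 did not pass (0.92 ± 0.52, edgeR adjusted p = 0.206), but passed without KO AC 1 (0.0464), without KO FAC 4 (0.0186) and without both (2.41e-05). Its levels were 8.26, 3.49 and 2.56 CPM in the KO AC libraries and 2.93, 10.8 and 13.3 CPM in the KO FAC libraries. They follow the division on the third principal component, and these fits drop the highest AC or the lowest FAC library. Those passes therefore cannot be assigned to FAC. Bile acid transport genes had 9 higher and 2 lower of 15 (adjusted over the list alone, 9 and 2; camera adjusted p = 0.00735, and adjusted p = 0.194 with an estimated correlation), with the uptake transporter genes Slc10a1 (1.01 ± 0.12) and Slco1b2 (1.25 ± 0.23) among them. The call was lost under the stricter filter (0.575) and without KO AC 1 and KO FAC 6 (0.087). The metallothionein genes Mt1 (1.07 ± 0.13) and Mt2 (1.04 ± 0.18) rose, as did 4 of 6 members of their list (adjusted over the list alone, 4; camera adjusted p = 0.00735, and adjusted p = 0.29 with an estimated correlation). The metallothionein call was lost without KO AC 1 and KO FAC 4 (0.144). Haem metabolism had 4 of 12 higher (adjusted over the list alone, 4; camera adjusted p = 0.00724, and adjusted p = 0.215 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 10 higher and 1 lower of 28 (adjusted over the list alone, 14 and 1; camera adjusted p = 0.00821, and adjusted p = 0.627 with an estimated correlation). The latter call was lost without KO AC 3 (0.078) and with TPM values (0.0771), where the median was −0.002. Acute-phase genes had 10 higher and 4 lower of 23 (adjusted over the list alone, 12 and 5; camera adjusted p = 0.0394, and adjusted p = 0.561 with an estimated correlation). That call was lost without KO AC 2 (0.06), KO AC 3 (0.078), KO FAC 4 (0.125) or KO FAC 5 (0.102) and under 5 other settings, at camera adjusted p from 0.0557 to 0.0995.

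Fewer lists fell in KO cells. Interferon response genes had 11 lower and 1 higher of 21 (adjusted over the list alone, 11 and 1; median −0.41; camera adjusted p = 0.000168, and adjusted p = 0.351 with an estimated correlation). Oasl2 (−1.18 ± 0.18), Ifi44 (−1.10 ± 0.20) and Ifit1 (−1.09 ± 0.23) were lower, and Cxcl9 was higher (0.84 ± 0.09). The NF-κB inflammation list had a median of −0.84 (camera adjusted p = 0.00277, and adjusted p = 0.599 with an estimated correlation), but only 1 of its 22 members passed (adjusted over the list alone, 0). That member, Tnf, was lost under 8 alternatives, at edgeR adjusted p from 0.0525 to 0.221. Among these were KO AC 1 (0.134), KO AC 2 (0.0907), KO AC 3 (0.0525) and KO FAC 4 (0.108) left out. Among p53 targets 5 fell and 1 rose of 18 (adjusted over the list alone, 5 and 1; camera adjusted p = 0.0256, and adjusted p = 0.192 with an estimated correlation), with Pmaip1 from 2.81 to 0.13 CPM (−4.44 ± 0.50) and Fas at −1.23 ± 0.22. That list was not called without KO AC 2 (0.0669) or KO FAC 6 (0.0526), under the stricter filter (0.177), or with the 3 FPKM and TPM scalings (0.0574 to 0.0651). In WT cells it also had 5 lower and 1 higher with FAC (median −0.19), without a call (camera adjusted p = 0.0776). The BMP and hepcidin list had 8 lower and 2 higher of 15 (adjusted over the list alone, 8 and 2) but was not called (camera adjusted p = 0.0977). In it Id1 (−1.37 ± 0.18), Id2 (−1.55 ± 0.31) and Atoh8 (−2.83 ± 0.35) fell, and Smad7 did not pass (0.11 ± 0.17). The iron uptake, storage and export list (5 higher, 4 lower and 12 not passing) and the heat-shock list (3 higher, 9 not passing) were not called (camera adjusted p = 0.857 and 0.561). Adjusted over each list alone, 5 were higher and 4 lower, and 3 higher and 1 lower. Hspa1a rose by 1.10 ± 0.20. Slc7a11, Gpx4 and Nr0b2 did not pass in KO cells (edgeR adjusted p = 0.537, 0.483 and 0.729). Lists of macrophage, endothelial, stellate and cholangiocyte markers were not called in KO cells with FAC (camera adjusted p = 0.727, 0.862, 0.595 and 0.123). The macrophage and stellate medians lay above 0 and their means below it, and the endothelial median lay below 0 where the test pointed up. On the log2(FPKM + 1) scale 12 of 118 named genes had folds over 1.5 times smaller, Abcb11, Atoh8, Hspa1a and Pmaip1 among them. With TPM values 34 had, these 4 and Fth1 among them. With KO AC 1 and KO FAC 4 left out, where treatment coincides with the third principal component, 6 had larger folds, Hamp among them.

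Whether FAC acted differently in the genotypes was tested as the FAC effect in KO cells minus that in WT cells. The rise of Hspa1a was 4.61 on the log2 scale in WT and 1.10 in KO cells, a difference of −3.51 ± 0.28 (SE, n = 3 per group, edgeR adjusted p = 3.04e-05), and that of Hspa1b differed by −3.01 ± 0.21. Their summed reads were higher in KO cells under AC (18.8 against 9.05 CPM in WT, log2 fold change 1.06 ± 0.14, edgeR adjusted p = 6.95e-05) and lower under FAC (25.2 against 113 CPM, −2.16 ± 0.13). Ddit3 rose less in KO cells (−1.13 ± 0.13, edgeR adjusted p = 0.000558), whereas Phgdh (0.94 ± 0.10) and Creld2 (1.09 ± 0.11) rose more. Hamp fell less in KO cells, by a difference of 3.14 ± 0.54 (edgeR adjusted p = 0.0215), and the difference of the summed reads of Hamp and Hamp2 was 3.54 ± 0.45 (edgeR adjusted p = 0.00681). The Hamp call was lost without WT AC 2 (0.0593), WT AC 3 (0.0597) or WT FAC 4 (0.0562), in a range from 1.89e-06 over its alternatives. Sprr1a, a cornified envelope gene, fell from 539 to 113 CPM in WT cells and was at 956 and 939 CPM in KO cells (2.23 ± 0.15), and Avpr1a, a vasopressin receptor gene, differed by 2.70 ± 0.32. For Tfrc (−0.67 ± 0.23), Ftl1 (0.24 ± 0.11), Fth1 (0.23 ± 0.13), Slc40a1 (0.26 ± 0.26) and Id1 (0.61 ± 0.24) no difference was called (edgeR adjusted p = 0.132, 0.26, 0.379, 0.626 and 0.182), which does not show that they responded alike. Nor was one called for Slc7a11, Gpx4, Smad7, Nr0b2, Cyp8b1 or Nr1h4 (edgeR adjusted p = 0.917, 0.666, 0.196, 0.606, 0.964 and 0.908). With KO AC 1 and KO FAC 4 left out, a difference was called for Ftl1 (0.38), Slc40a1 (0.65), Id1 (0.93), Nr0b2 (2.82) and Cyp8b1 (1.20), at edgeR adjusted p = 0.0203, 0.0113, 0.00741, 0.022 and 0.0361. In that fit treatment in KO cells coincides with the division on the third principal component, so these added calls cannot be assigned to FAC.

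In all, 387 genes differed (3.15%; edgeR quasi-likelihood, Benjamini-Hochberg), 230 with a higher and 157 with a lower effect in KO cells, and 100 by at least 2-fold. The count depended on single libraries. Without KO AC 1, 2 or 3 it was 591, 190 and 176. Without KO FAC 4 or 5 it was 656 and 169. Without WT AC 2 or 3 it was 138 and 93, and without WT FAC 4, 5 or 6 it was 136, 148 and 147. DESeq2 called 678, and the fit with the replicate number as a block called 84. With KO AC 1 and KO FAC 4 left out 1932 genes were called, in the fit where treatment in KO cells coincides with the third principal component. The share with a higher effect was 45.3% with log2(FPKM + 1), 43.5% with a pseudocount of 0.1 and 40.5% with TPM values, against 59.4% here.

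Of 33 lists, 12 differed, and heat shock alone (3 of 12 members lower, adjusted over the list alone 3; median −0.09; camera adjusted p = 9.4e-07) was also called with an estimated correlation (0.0126). Without Hspa1a and Hspa1b the other 10 members had a median of −0.061 and an unadjusted camera p of 0.242. The pericentral list had 3 of 16 members with a higher effect in KO cells (adjusted over the list alone, 9 higher and 1 lower; camera adjusted p = 0.000212, and adjusted p = 0.172 with an estimated correlation). The xenobiotic list had 3 of 21 higher (adjusted over the list alone, 7 and 1; camera adjusted p = 0.00241, and adjusted p = 0.137 with an estimated correlation). It shares Cyp1a2, Cyp2a5 and Cyp2e1 with the pericentral list, so the calls of these lists are not separate results. The BMP and hepcidin list had 2 of 15 higher, Hamp and the receptor decoy gene Bambi (adjusted over the list alone, 3 and 1; camera adjusted p = 0.00922, and adjusted p = 0.172 with an estimated correlation). The call of Bambi (1.72 ± 0.32) was lost with the replicate block (0.0718). Bile acid transport had 2 of 15 higher, Slc10a1 and Abcb11 (adjusted over the list alone, 6; camera adjusted p = 0.0124, and adjusted p = 0.254 with an estimated correlation). That call was lost under the stricter filter (0.108) and without KO AC 1 and KO FAC 6 (0.0866). Slc10a1 (1.14 ± 0.20) was lost with the replicate block (0.0568), and Abcb11 (1.11 ± 0.26, edgeR adjusted p = 0.0392) in 12 of 22 alternatives, at up to 0.0975 without WT FAC 4. Haem metabolism had 1 of 12 higher (adjusted over the list alone, 1; camera adjusted p = 0.0208, and adjusted p = 0.296 with an estimated correlation). That gene was Hmox1 (1.09 ± 0.25, edgeR adjusted p = 0.0418), whose call was lost in 12 of 23 alternatives, at up to 0.101 without WT AC 3. Cell cycle genes had 1 of 22 higher (adjusted over the list alone, 2; camera adjusted p = 0.00525, and adjusted p = 0.263 with an estimated correlation), a call lost under the stricter filter (0.0558). Dedifferentiation genes had 4 of 26 higher (adjusted over the list alone, 9; camera adjusted p = 0.00769, and adjusted p = 0.296 with an estimated correlation), a call lost without KO AC 1 and KO FAC 4 (0.0745). Among them was the intermediate filament gene Vim (0.82 ± 0.13).

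For 4 further lists no member passed over all genes. Among these were interferon response (adjusted over the list alone, 7 lower; median −0.30; camera adjusted p = 0.000791, and adjusted p = 0.46 with an estimated correlation) and NF-κB inflammation (adjusted over the list alone, 0; median −0.48; camera adjusted p = 0.0161, and adjusted p = 0.633 with an estimated correlation). The others were metallothionein (adjusted over the list alone, 2 higher; median 0.37; camera adjusted p = 0.0307, and adjusted p = 0.432 with an estimated correlation) and sinusoidal endothelial markers (adjusted over the list alone, 1 lower; median −0.65; camera adjusted p = 0.0307, and adjusted p = 0.261 with an estimated correlation). The inflammation call was lost without KO FAC 6 (0.413), without WT AC 1 (0.0546) and under 3 other settings. The metallothionein call was lost without KO AC 1 (0.148), KO FAC 4 (0.142) or WT FAC 6 (0.0699) and under 6 others. The endothelial call was lost without KO AC 1 (0.111), KO AC 2 (0.0538), KO FAC 6 (0.0801), WT AC 1 (0.0693) or WT FAC 6 (0.0699) and under 5 others. Of the 41 genes named for this comparison, 15 kept their call under every alternative run, among them Hspa1a, Hspa1b, Ddit3, Phgdh, Creld2, Sprr1a and Avpr1a. The difference was over 1.5 times smaller for 5 of 39 of them on the log2(FPKM + 1) scale, Avpr1a and Abcb11 among them, and for 3 with TPM values, Abcb11 among them.

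The FAC effects in the genotypes were compared across the 12275 genes, which are not independent replicates. They correlated at Pearson r = 0.499 and Spearman rho = 0.499, and r was 0.182 with no filter on low counts. Genes higher in both genotypes numbered 585 (160 expected by chance), genes lower in both 587 (153 expected), and 34 changed in opposite directions.

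The comparison of the genotypes under AC asked how KO and WT cells differed without FAC. Of 18 major urinary protein genes tested, 10 were higher and 4 lower in KO cells, and the rest did not pass. Furthest apart in each direction were Mup9, at 8.26 ± 0.40 CPM in WT and 9348 ± 1105 CPM in KO cells (SD, n = 3; log2 fold change 10.14 ± 0.12, SE), and Mup14, at 1351 ± 96.4 and 27.0 ± 1.1 CPM (−5.65 ± 0.09). Liver enzyme genes were higher in KO cells: Arg1 of the urea cycle (4.59 ± 0.15), Hal of histidine breakdown (4.84 ± 0.31), Hpd of tyrosine breakdown (4.21 ± 0.14) and the P450 gene Cyp2e1 (118 to 752 CPM, 2.68 ± 0.09). Hamp2 was at 0.15 CPM in WT and 12.1 CPM in KO cells (6.31 ± 0.27), while Hamp did not pass (−0.54 ± 0.36, edgeR adjusted p = 0.25). Abcb11 was lower in KO cells (6.10 to 2.18 CPM, −1.48 ± 0.19, edgeR adjusted p = 4.7e-05), as were Id1 (−1.44 ± 0.16), Slc40a1 (−0.92 ± 0.19) and Slc7a11 (−1.52 ± 0.21).

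Under AC 5265 genes differed between KO and WT cells (42.9%; edgeR quasi-likelihood, Benjamini-Hochberg), 2667 higher and 2598 lower in KO cells, 1253 of them at least 2-fold, and the libraries of 6502 genes (53%) did not overlap (chance 10%). The share that was higher was 37.7% with log2(FPKM + 1), 37.9% with a pseudocount of 0.1 and 31.5% with TPM values (median shift −0.117), against 50.7% here.

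Liver function lists rose in KO cells. Those also called with an estimated correlation were xenobiotic enzymes (15 higher and 2 lower of 21, median 2.01, camera adjusted p = 2.23e-29), periportal genes (13 and 2 of 16, 1.55, 3.86e-22), hepatocyte identity (16 and 3 of 23, 1.22, 6.73e-20), pericentral genes (12 and 0 of 16, 1.02, 3.97e-14) and gluconeogenesis and glycolysis (15 and 1 of 20, 0.81, 1.15e-06). Adjusted over the list alone, xenobiotic enzymes had 16 higher and 2 lower and the other 4 lists the same counts as over all genes. These lists share members, so their calls under either treatment are not separate results. Hal, Arg1, Ass1 and Cps1 are in the identity and periportal lists, and Pck1 and Sds in the periportal and gluconeogenesis lists. Cyp2e1, Cyp1a2 and Cyp2a5 are in the xenobiotic and pericentral lists. Beside these lists, markers of other liver cells were lower: the stellate list had 10 lower and 1 higher of 13 (adjusted over the list alone, 11 and 1; median −1.78; camera adjusted p = 1.06e-06, and 0.012 with an estimated correlation), with Dcn from 2.48 to 0.11 CPM. The macrophage list had 6 lower and 2 higher of 9 (adjusted over the list alone, 7 and 2; camera adjusted p = 0.0216, and adjusted p = 0.206 with an estimated correlation), with Adgre1 from 2.23 to 0.32 CPM. It was not called with the 3 FPKM and TPM scalings (0.33 to 0.438). Endothelial markers had 8 lower and 4 higher of 14 (adjusted over the list alone, 8 and 5) and no call (camera adjusted p = 0.632). The cholangiocyte marker Spp1, osteopontin, fell from 361 to 52.2 CPM in a list with no call (1 lower, 2 higher of 9, camera adjusted p = 0.995) whose median lay above 0 where the test pointed down.

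Lists of bile acid synthesis and lipid genes were higher as well, but their calls were lost with an estimated correlation. Bile acid synthesis had 9 of 16 higher (median 0.72; camera adjusted p = 2.59e-08, and adjusted p = 0.0924 with an estimated correlation), with Akr1c6 at 3.80 ± 0.20. Cyp8b1, the sterol 12-hydroxylase gene, passed in the full fit (1.82 ± 0.62, edgeR adjusted p = 0.0364), but not without KO AC 1 (log2 fold change 1.17, edgeR adjusted p = 0.159), WT AC 1 (0.0854), WT AC 2 (0.0904) or WT AC 3 (0.0983) and under 4 other settings. Cholesterol synthesis had 19 higher and 1 lower of 25 (camera adjusted p = 2.59e-08, and adjusted p = 0.0661 with an estimated correlation), and PPARα targets and fatty acid oxidation 14 of 25 higher (camera adjusted p = 8.73e-06, and adjusted p = 0.237 with an estimated correlation). Lipogenesis had 12 higher and 2 lower of 20 (camera adjusted p = 0.000169, and adjusted p = 0.117 with an estimated correlation), with the desaturase gene Scd1 at 1.61 ± 0.08. Adjusted over the list alone, these 4 lists had 9, 20, 15 and 12 higher. The acute-phase list had 12 higher and 4 lower of 23 (adjusted over the list alone, 12 and 4; camera adjusted p = 2.69e-12, and adjusted p = 0.0508 with an estimated correlation), with Serpina3n at 2.25 ± 0.09. Genes listed as induced by Fxr had 12 higher and 4 lower of 21 (adjusted over the list alone, 12 and 4; camera adjusted p = 0.0239, and adjusted p = 0.372 with an estimated correlation), a call lost without WT AC 1 (0.0615). In that list Fga (2.32 ± 0.13) and Fgg (2.17 ± 0.14) were higher in KO cells, and Abcb11 and the esterase gene Ces1g (−1.83 ± 0.13) were lower. Nr0b2, at only 1.03 CPM in WT AC and 0.438 CPM in KO AC, did not pass (−1.23 ± 0.63, edgeR adjusted p = 0.132) but did without KO AC 1 (−2.34, edgeR adjusted p = 0.018). Interferon response had 17 of 21 higher (adjusted over the list alone, 17; camera adjusted p = 1.91e-05, and adjusted p = 0.245 with an estimated correlation), Cxcl9 at 1.70 ± 0.10. The list of endoplasmic reticulum stress and the integrated stress response had 17 higher and 4 lower of 27 (adjusted over the list alone, 17 and 4; camera adjusted p = 0.000127, and adjusted p = 0.132 with an estimated correlation), Phgdh among the lower genes (−1.44 ± 0.07).

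Dedifferentiation genes had 12 higher and 3 lower of 26 (adjusted over the list alone, 15 and 4; camera adjusted p = 0.0216, and adjusted p = 0.245 with an estimated correlation), a call lost without WT AC 1 (0.06). The p53 targets had 8 of 18 higher (adjusted over the list alone, 8; camera adjusted p = 0.0412, and adjusted p = 0.143 with an estimated correlation), a call lost without KO AC 2 (0.0631), KO AC 3 (0.0506) or WT AC 1 (0.051) and under the stricter filter (0.078). Cell cycle genes had 8 of 22 lower (adjusted over the list alone, 8; camera adjusted p = 0.00385, and adjusted p = 0.168 with an estimated correlation), Mcm2 at −1.24 ± 0.11. Nrf2 targets had 15 lower and 5 higher of 30 (adjusted over the list alone, 15 and 5; camera adjusted p = 0.00464, and adjusted p = 0.0625 with an estimated correlation). The iron uptake, storage and export list had 10 lower and 4 higher of 21 (adjusted over the list alone, 10 and 4) without a call (camera adjusted p = 0.161). In it Tfrc was at −0.47 ± 0.16 (edgeR adjusted p = 0.029), a call lost without KO AC 2 (0.115), WT AC 1 (0.111) or WT AC 2 (0.0622). The BMP and hepcidin list was not called either (camera adjusted p = 0.632), with a median of −0.19 and a mean of 0.21. Ftl1 was at 0.21 ± 0.08 (edgeR adjusted p = 0.0419), a call lost in 12 of 18 alternatives: without KO AC 1 (log2 fold change 0.12, edgeR adjusted p = 0.186), KO AC 2 (0.0664), WT AC 1 (0.159) or WT AC 2 (0.0513), with the replicate block (0.092), and under 7 others at up to 0.3. Fth1, Hmox1, Gpx4 and Smad7 did not pass (edgeR adjusted p = 0.878, 0.485, 0.111 and 0.899), though Gpx4 did without KO AC 3 (0.0235). On the log2(FPKM + 1) scale 29 of 119 named genes had folds over 1.5 times smaller, Abcb11, Dcn, Cyp8b1 and Ftl1 among them, and with TPM values 26 had, these 4 among them.

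The last comparison set the genotypes side by side under FAC. Hamp was at 15.7 ± 5.3 CPM in WT and 94.8 ± 41.5 CPM in KO cells (SD, n = 3; log2 fold change 2.59 ± 0.40, SE, edgeR adjusted p = 0.000626), and all 3 KO libraries lay above all 3 WT libraries. Hspa1a was lower in KO cells (−2.61 ± 0.17), as were Hspa1b (−1.92 ± 0.14), Tfrc (−1.14 ± 0.17) and Gclc (−1.67 ± 0.11). Hmox1 was higher (1225 to 2335 CPM, 0.93 ± 0.18, edgeR adjusted p = 0.0012), and so was Ftl1 (0.45 ± 0.08). Mup9 (9.93 ± 0.11), Hal (5.41 ± 0.29), Hpd (4.66 ± 0.13) and Cyp2e1 (3.12 ± 0.09) were again far higher in KO cells. Abcb11 did not pass here (−0.37 ± 0.18, edgeR adjusted p = 0.102).

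Under FAC 6071 genes differed between the genotypes (49.5%; edgeR quasi-likelihood, Benjamini-Hochberg), 3018 higher and 3053 lower in KO cells and 1504 at least 2-fold. Libraries did not overlap for 7260 genes (59.1%; chance 10%). The share that was higher was 32.9% with log2(FPKM + 1) and also with a pseudocount of 0.1, and 26.1% with TPM values, against 49.7% here. The median shifts over all genes of these settings were −0.13, −0.147 and −0.198.

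The 5 liver function lists were higher again and were called with either correlation: xenobiotic enzymes (15 higher and 1 lower of 21, median 2.41), periportal (12 and 2 of 16, 1.79), pericentral (14 and 1 of 16, 1.79), hepatocyte identity (15 and 1 of 23, 1.20) and gluconeogenesis and glycolysis (15 and 1 of 20, 1.19). Their camera adjusted p ran from 4.1e-34 to 2.81e-07. Adjusted over the list alone, they had 15, 13, 14, 15 and 16 higher. The heat-shock list fell, with 9 lower and 1 higher of 12 (adjusted over the list alone, 9 and 1; median −0.41; camera adjusted p = 0.000212, and 0.0191 with an estimated correlation), Hsp90aa1 at −0.91 ± 0.09 and Dnaja1 at −0.94 ± 0.08. Markers of other cells lay lower beside them. The stellate list had 9 lower and 1 higher of 13 (adjusted over the list alone, 9 and 1; median −2.73; camera adjusted p = 0.00162, and adjusted p = 0.0614 with an estimated correlation), and was not called with the 3 FPKM and TPM scalings (0.15 to 0.181). The macrophage list (6 lower and 2 higher of 9, median −2.35) and the endothelial list (8 lower and 4 higher of 14, median −1.66) missed the threshold (camera adjusted p = 0.059 and 0.0657). Adjusted over each list alone, 7 and 8 of their members were lower, among them the endothelial marker Cdh5 from 9.10 to 1.17 CPM.

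The BMP and hepcidin list was higher in KO cells under FAC, with 6 higher and 4 lower of 15 (adjusted over the list alone, 6 and 4; median 0.45; camera adjusted p = 0.0191, and adjusted p = 0.0886 with an estimated correlation). It was not called with no filter (0.149) or with the 3 FPKM and TPM scalings (0.153 to 0.203). Tmprss6, a protease gene that restrains hepcidin, was at 1.22 ± 0.09 and Id1 at −0.83 ± 0.18. Smad7 passed (0.55 ± 0.17, edgeR adjusted p = 0.0149), but not without KO FAC 4 (0.0575) or with those scalings (0.0592 to 0.126). Bile acid synthesis had 11 of 16 higher (adjusted over the list alone, 11; camera adjusted p = 1.31e-08, and adjusted p = 0.0886 with an estimated correlation), with Cyp8b1 at 1.93 ± 0.56 (edgeR adjusted p = 0.0144, and 0.0532 without WT FAC 4). Bile acid transport had 10 higher and 2 lower of 15 (adjusted over the list alone, 11 and 2; camera adjusted p = 0.0266, and adjusted p = 0.163 with an estimated correlation). That call was lost without KO FAC 6 (0.0573), WT FAC 6 (0.0516) or KO AC 1 and KO FAC 6 together (0.0718), and with log2(FPKM + 1) (0.0819) or a pseudocount of 0.1 (0.092), and the direction of the test turned under the stricter filter (0.854). Genes listed as induced by Fxr had 11 higher and 3 lower of 21 (adjusted over the list alone, 12 and 3; camera adjusted p = 0.0022, and adjusted p = 0.214 with an estimated correlation). Cholesterol synthesis had 21 of 25 higher (adjusted over the list alone, 21 and 1 lower; camera adjusted p = 1.25e-08, and adjusted p = 0.0695 with an estimated correlation). PPARα targets had 15 higher and 2 lower of 25 (adjusted over the list alone, 15 and 3; camera adjusted p = 0.000143, and adjusted p = 0.278 with an estimated correlation). Lipogenesis had 13 of 20 higher (adjusted over the list alone, 13; camera adjusted p = 0.00016, and adjusted p = 0.0993 with an estimated correlation). The acute-phase list had 11 higher and 5 lower of 23 (adjusted over the list alone, 12 and 6; camera adjusted p = 2.78e-10, and adjusted p = 0.0695 with an estimated correlation). Endoplasmic reticulum and integrated stress genes had 16 higher and 2 lower of 27 (adjusted over the list alone, 16 and 3; camera adjusted p = 1.96e-05, and adjusted p = 0.0886 with an estimated correlation). Dedifferentiation genes had 16 higher and 1 lower of 26 (adjusted over the list alone, 17 and 1; camera adjusted p = 0.000306, and adjusted p = 0.0932 with an estimated correlation). Slc40a1 (−0.66 ± 0.18) and Slc7a11 (−1.44 ± 0.21) were lower, and Gpx4 and Nr0b2 did not pass (edgeR adjusted p = 0.537 and 0.917). Fth1 was at 0.25 ± 0.09 (edgeR adjusted p = 0.0435), a call lost in 12 of 18 alternatives, among them those without KO FAC 4 (log2 fold change 0.15, edgeR adjusted p = 0.169), KO FAC 5 (0.0824), WT FAC 4 (0.0562), WT FAC 5 (0.097) or WT FAC 6 (0.126), and at up to 0.669 with TPM values. On the log2(FPKM + 1) scale 30 of 120 named genes had folds over 1.5 times smaller, Cdh5, Cyp8b1, Smad7 and Fth1 among them, and with TPM values 33 had, these 4 and Ftl1 among them.

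**Figure D2:**
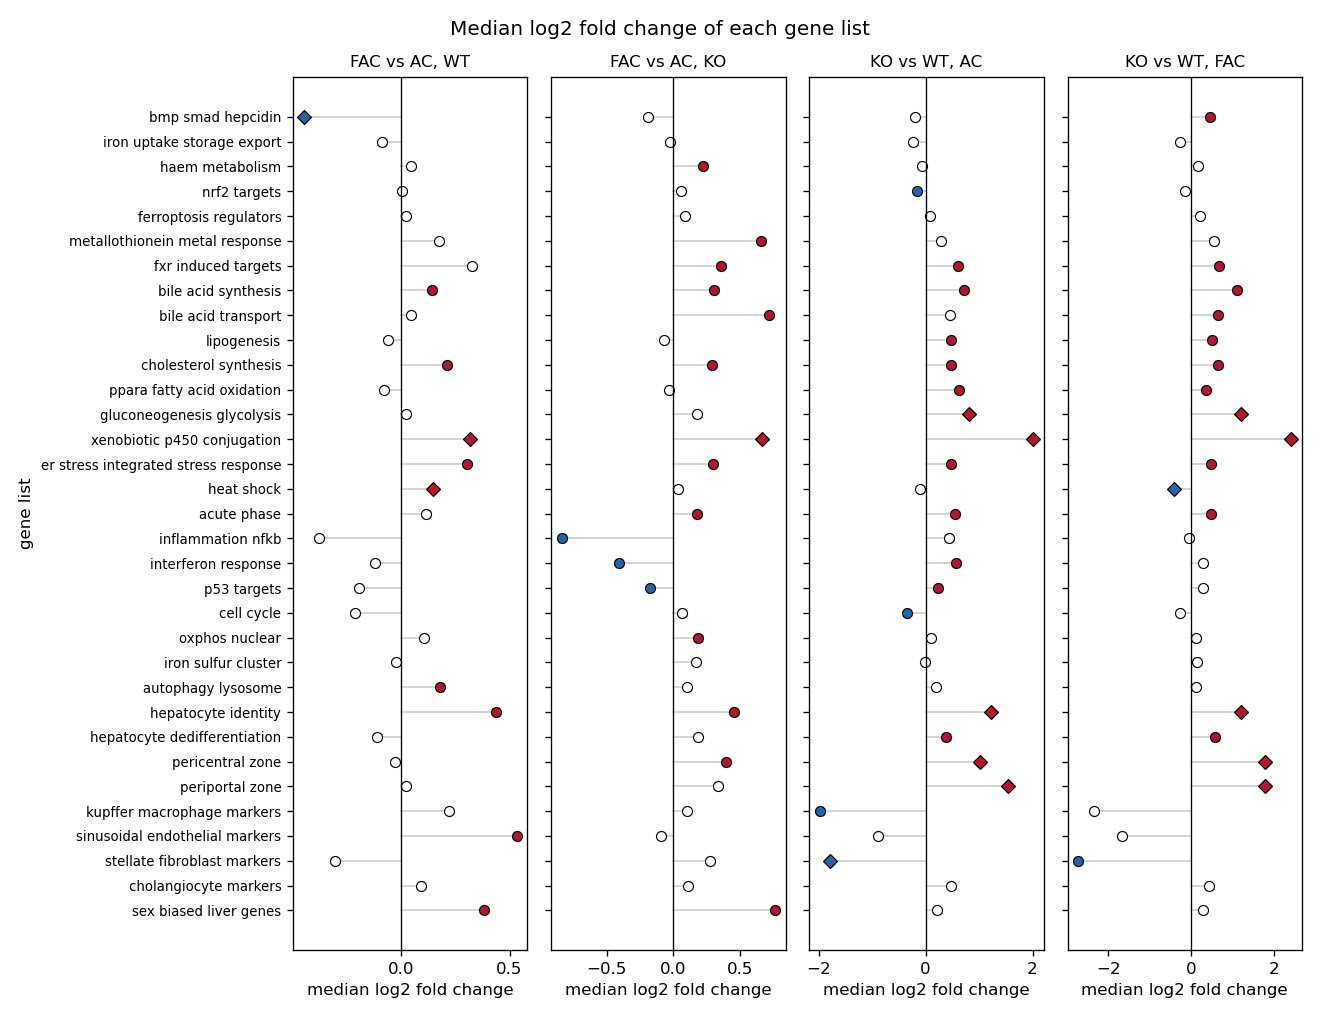
Median log2 fold change of each of 33 gene lists (points) in the 4 comparisons of groups (panels, whose horizontal axes differ in range); red and blue points are lists called higher and lower by camera, white points were not called, and diamonds mark lists also called with an estimated correlation. The xenobiotic enzyme list sits at 0.32, 0.67, 2.01 and 2.41 for FAC in WT, FAC in KO, KO under AC and KO under FAC.

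The genotype effects under AC and FAC correlated across genes at Pearson r = 0.84 and Spearman rho = 0.764, and r was 0.539 with no filter on low counts. Genes higher in KO cells under both treatments numbered 1976 (656 expected by chance), genes lower under both 1876 (646 expected), and 54 changed in opposite directions.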

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

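Of the tests in this part, those of the Nr1h4 region, of the lower Mup genes, of cell purity and dedifferentiation, of preparation, and of Hspa1a and Hspa1b without each library were chosen only after the result was seen. The tests of summed reads, of strain variants elsewhere in the genome and of the other heat-shock genes were chosen after the values of single genes were seen, but before their own results were. The counts of other splits were set before their results were seen.

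Hspa1a and Hspa1b rose more with FAC in WT than in KO cells, with differences of −3.51 and −3.01 on the log2 scale. Part of this lies in the AC libraries, where their summed reads were higher in KO by a log2 fold change of 1.06 (−2.16 under FAC). A single library is argued against, since the highest edgeR adjusted p of either gene with 1 library left out was 0.000363. Reads assigned to the wrong one of these near-identical genes are argued against as well, since both differed in the same direction. Their summed reads differed by −3.22, which follows from the single values and is no separate support. Whether the difference belongs to a broader heat-shock response stays open: the other 10 heat-shock genes had a median difference of −0.061 and were not called as a list by camera, with Dnaja1 the only one called lower (−0.47). That call was lost in 14 of 23 alternatives, at edgeR adjusted p up to 0.144 without WT AC 3. These included each KO library and WT AC 2, WT AC 3 and every WT FAC library left out in turn. A weaker response of these genes to FAC without Fxr may be the biological explanation, and it is a hypothesis that these samples cannot separate from other differences between the WT and KO cells.

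Genes at least 8-fold apart between the genotypes under both treatments numbered 110, of which 80 were higher in KO, on 19 chromosomes. Of the 109 with a position, 5 lay within 10 Mb of Nr1h4 (Prtn3, Jsrp1, Gm32687, Spic and Hal), a share of 4.59% against 1.46% of the other tested genes (two-sided Fisher exact p = 0.0232), so variants carried along with the knocked-out locus may contribute there. Hal also belongs to the hepatocyte identity list, which was higher in KO as a whole. For the rest the window does not decide. A longer carried segment could hold further genes of chromosome 10, such as Arg1 or Trhde, and effects of carried variants on distant genes were not tested. Strain variants elsewhere in the genome stay open. Of these genes 20 had another within 1 Mb whose symbol differs before its first digit. Random sets of tested genes had a mean of 17.8 (one-sided permutation p = 0.361). Neighbours of one family, such as Mup9 and Mup1, were not counted, so the test does not show that these genes lie scattered. Variants spread singly would leave no cluster. In the Mup family the summed reads were higher in KO, by a log2 fold change of at least 1.77 under either treatment, which argues against misassigned reads as the source of the gain. The members that were lower under AC lost 7.32% of what the others gained. A higher sum makes the loss smaller than the gain whatever lowered them, so misassignment stays open for these members.

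Hepatocyte identity genes were higher in KO, and some markers of other liver cells were lower. The stellate list was called lower under both treatments, and with an estimated correlation under AC only. The macrophage list was called lower under AC only, a call lost with an estimated correlation. The endothelial list was not called under either treatment, nor the cholangiocyte list under AC. Fewer cells of other types could lower those markers, and only 1 identity gene (Alb) was called lower under both treatments (Apob and Cebpa under AC only), which leaves that explanation open for them. For the rise of the identity genes it is argued against as the only cause, since a larger hepatocyte share would lift them alike and the interquartile range of their log2 fold changes under AC was 1.82. A common lift beside differences of single genes would leave such a spread too, so a partial contribution stays open. Cultures that were less dedifferentiated would have the dedifferentiation list lower in KO. It lay higher under both treatments instead (smaller median 0.39), the opposite direction. That explanation is not excluded, since the call of the list was lost with an estimated correlation. Fxr loss cannot be told apart from a difference in preparation or strain, since the labels name no preparation that holds both genotypes. The gap of at least 65.0 between WT and KO libraries on the first principal component is what either would give and decides nothing. A check of sex was planned, and Y-linked genes were read in every library. Mean CPM in WT and KO under AC was 62.2 and 35.0 for Ddx3y, 27.6 and 15.8 for Kdm5d, and 24.9 and 14.7 for Uty. These genes were lower in KO under FAC too (61.1 and 25.8, 23.9 and 12.1, 22.3 and 9.85). Eif2s3y was not lower (56.6 and 71.2 under AC, 56.9 and 57.2 under FAC). The cause was not tested.

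The test of the difference between the FAC effects picked out 387 genes, and 8 of 100 splits of the libraries gave at least as many. This share does not exclude chance, but it does not measure chance either. The highest other split, with 4477 genes, exchanged AC and FAC in KO cells alone and so tested the sum of the FAC effects. All 7 other splits that reached the real count kept the treatment groups of at least 1 genotype whole. Such splits carry a FAC effect into the contrast, so their share decides nothing about chance. The 80 splits that kept neither whole reached at most 4, a description made after the counts were seen. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. FAC in WT gave 2117 genes and the highest other split 0, with 1 split at least as high, the real one. FAC in KO gave 3633 and the highest other 727, again with 1 split at least as high. That other split set KO AC 1, KO FAC 5 and KO FAC 6 against the other KO libraries, which follows the third principal component and not the treatment. KO against WT gave 5265 genes under AC and 6071 under FAC, with 0 in the highest other split of each and 1 split as high, the real one.

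The same test of the difference picked out 12 lists. The effect was higher in KO cells in bile acid transport (median 0.41), xenobiotic enzymes (0.40), pericentral genes (0.38), metallothionein genes (0.37), cell cycle (0.30), the BMP and hepcidin list (0.23), dedifferentiation (0.21) and haem metabolism (0.15). It was lower in sinusoidal endothelial markers (−0.65), inflammation (−0.48), interferon response (−0.30) and heat shock (−0.085). With an estimated correlation only heat shock was called.

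Single genes with a higher effect in KO cells included Hamp (3.14), Avpr1a (2.70), Cryab (2.26), Sprr1a (2.23), Fgfr4 (2.21), Krt20 (2.08), Sprr1b (1.92), Bambi (1.72), Star (1.53), Hgd (1.43), Cps1 (1.18), Aurka (1.15), Slc10a1 (1.14), Abcb11 (1.11), Hmox1 (1.09), Creld2 (1.09), Fga (0.98), Phgdh (0.94), Fgb (0.91), Cyp4a10 (0.84), Vim (0.82), Cyp2d22 (0.72), Lgals3 (0.50), Cyp1a2 (0.49), Krt18 (0.44), Cyp2a5 (0.44) and Tkt (0.35), on the log2 scale. Besides Hspa1a, Hspa1b and Dnaja1, those with a lower effect were Dhrs9 (−1.22), Uox (−1.22), Dnmt3a (−1.21), Spin4 (−1.13), Ddit3 (−1.13), Stc2 (−1.09), Vnn1 (−0.70), Gclc (−0.66) and Acot2 (−0.65). The calls of Hspa1a, Hspa1b, Avpr1a, Cryab, Sprr1a, Fgfr4, Sprr1b, Cps1, Creld2, Fga, Phgdh, Cyp4a10, Vim, Spin4 and Ddit3 held in every refit. Each of the others was lost in 1 to 16 alternatives, at edgeR adjusted p up to 0.144. Bambi, Slc10a1 and Dnmt3a were lost with the replicate block alone, and the rest also without single libraries.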

How the results depend on the processing

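DESeq2, scaling without Mup genes, and the fits without KO AC 1 and KO FAC 6 or without KO AC 1 and KO FAC 4 were chosen after seeing the data. The other alternatives were fixed before, limma on log2(FPKM + 1) in the plan of tests and not in the list of alternatives. In 9816 refits of named genes no called gene turned its direction. Of these refits 9188 kept the gene on its side of the threshold, 610 lost a call and 18 gained one. Of 1339 refits of called lists at the preset correlation 1264 kept the call, 74 lost it and in 1 the direction of the test turned: bile acid transport in KO against WT under FAC, at a median of 0.093 among the genes left by the stricter filter. Of 541 calls of named genes 433 held in every refit, and of 74 list calls 55 did. The estimated correlation, which is not among these refits, ended 57 of the 74 list calls, and the 17 that it kept also held in every refit. The cause was not tested for any of the shifts below unless one is named.

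Fits of the compared pair of groups alone called 3352 genes for FAC in WT and 2198 in KO. A 2-fold threshold left 290, 487, 1253, 1504 and 100 genes for FAC in WT, FAC in KO, KO under AC, KO under FAC and the difference, as its construction requires. The difference had 678 genes with DESeq2, 1932 without KO AC 1 and KO FAC 4, and 84 with the replicate number as a block, which spends degrees of freedom. In the fit that called 1932, treatment in KO cells coincides with the third principal component. With that block 4670 genes were called in KO under AC and 5688 under FAC. The block gives no value for FAC against AC, because no number occurs under both treatments, and profiles of equal number did not pair between genotypes (r from −0.142 to 0.208). Estimated correlation left 3 of 10 lists for FAC in WT, 1 of 16 for FAC in KO, 1 of 12 for the difference, 6 of 19 for KO under AC and 6 of 17 for KO under FAC.

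With 1 library left out, counts ran from 1264 to 1663 for FAC in WT, 2365 to 4088 for FAC in KO, 93 to 656 for the difference, 4144 to 5045 for KO under AC and 5203 to 5910 for KO under FAC. The similarity of the FAC effects (r) ran from 0.449 to 0.508 and that of the genotype effects from 0.809 to 0.843. The former was 0.631 with the stricter filter, 0.182 with no filter, 0.578 with log2(FPKM + 1) and also with TPM, and 0.576 with a pseudocount of 0.1. The latter was 0.893, 0.539, 0.86 (also with TPM) and 0.862 under these settings, 0.828 with DESeq2, 0.825 without KO AC 1 and KO FAC 6, and 0.772 without KO AC 1 and KO FAC 4. Depth limits genes of few reads: 4453 genes were left untested, Cyp7a1 and Slc51b among them, and folds of low genes shrank on log2(FPKM + 1), whose added 1 pulls them in.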
